A study of Sus scrofa domesticus with 4 samples.

How the data were processed

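Anterior pituitaries of 4 pregnant and 4 cyclic gilts of about 110 kg were collected on days 12 to 13, per the labels' protocols, and 825 ng of labelled cRNA per dye was hybridised to each of 4 two-colour Agilent arrays of design 026440. The labels name 8 individuals, so each array compares a separate pair of animals; the arrays lie on 1 slide and were read in 1 scan, so there was no slide or scan batch to test. The labelling protocol reads as if pregnant RNA was always in Cy3, while the label of each sample alternates the dyes. The sample labels were used, and the other reading was an alternative.

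The deposited scanner files give, per the file headers, the spot and background intensity of Cy3 and Cy5 as read by Agilent Feature Extraction 10.7.3.1, with flags for spots above background, saturated spots and outliers. Per the file headers they also give processed signals, background-subtracted and dye-normalised within the array, and the log10 ratio of Cy5 over Cy3. The deposited value table of the series holds log2 ratios. Set against log2 of each array's processed Cy5 over Cy3 signals, its 4 columns had slopes of -1, 1, -1 and 1, an intercept of 0 and r of -1, 1, -1 and 1 over 43661 values, so it is a log2 ratio turned by the sample labels' dyes. Its column medians were 0.08, -0.08, -0.18 and -0.18, so it is not centred; what software made it is not given in the sources used here.

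The files used here hold median, not mean, signals, so the main setting ran on medians where the plan had named means. Background was corrected by normexp with an offset of 50 on median signal and median background, each array was normalised by loess with weight 0 for control spots, spots with an outlier flag were left out, and spots of 1 probe were averaged. Each ratio was turned to pregnant over cyclic. A probe was tested if well above background on all 4 arrays in the channel of at least 1 group, and if at least 3 arrays had an unflagged spot: 23913 probes met the first condition and 21627 both, 19880 on 4 arrays and 1747 on 3. Models were fitted by limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with the group difference and a dye effect for each probe, and p was adjusted by Benjamini-Hochberg over tested probes. Values after a plus-minus sign are SD over the arrays unless named as SE. The value before the sign is the fitted ratio. For probes on 3 arrays it is not the plain mean, since the array alone in its dye orientation weighs most in the fit.

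Gene names came from RefSeq accessions of the probes matched without versions to the NCBI table of pig genes: 5578 of 43603 probes had a name, for 2459 genes, and none of the 7823 probes with an Ensembl transcript ID did. Tested were 3440 named probes of 1744 genes and 18187 unnamed probes, which take part in all counts of probes. A gene is represented by its tested probe with the highest mean intensity, and 795 genes had several.

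The genes in the text follow a rule set before the data were examined: the largest changes among calls, or, with fewer than 5 calls in a direction, the 8 named genes with the smallest unadjusted p and the same sign on all arrays; every measured pituitary hormone gene and GNRHR, ESR1, PGR, FST and INHBB; and up to 4 genes with the smallest p in each other list. INHBB had no tested probe. Of the genes that this rule takes the text names 79, of which 17 were added, after the values were seen, so that lists with few examples had more, and 1 other is not reported here. The tested probes of a gene disagreed in sign for ADAM17, RPL6, POMC, ESR1, NR5A1, KLF2, HSD17B4, SLA-DQA1, PECAM1, FBN1, CCL5, CDH1, HSP90B1, HSP90AA1, SDHD, ATP5O and RPLP0. There were 29 lists, and 27 with at least 5 measured genes were tested with camera (preset correlation 0.01, on moderated statistics of 1744 genes), again with an estimated correlation, and with fry. Fry and the estimate of the correlation used only genes with a ratio on all 4 arrays. Fry thus held 6 of 7 hormone genes, without FSHB, and 3 of 5 neural markers. The lineage factor list, with 4 genes, and the erythrocyte list, with 0, were described only. The median, the mean and the camera direction of a list did not share a sign for antigen presentation, adipokines, angiogenic factors and prostaglandins.

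The fit was tested on simulated data with the real dye effects and the fitted distribution of variances, in 10 runs on 21627 probes with 200 changed probes each. Of probes changed 1.5-fold 4.2% were called, of those changed 2-fold 64.2%, 4-fold 94.0% and 8-fold 99.2%, and 4.92% of unchanged probes had an unadjusted p under 0.05. A list of 19 genes shifted by 0.5 on the log2 scale was called in 10 of 10 runs. The simulated noise was independent between probes and equally large on every array. In the real data the SD of the ratios ran from 0.276 to 0.581 over the arrays, and the estimated correlation within a list reached 0.957. The simulated shares therefore need not hold for the real data. The alternatives were other background corrections, offsets, normalizations, filters, priors and weights, no dye effect, a separate-channel fit on the 19880 probes of 4 arrays, the other dye orientation, leaving out each array, the deposited table, and the mean over the probes of a gene. Masking the dim area of array 4 and keeping flagged spots were added after seeing the data. Levels per gilt are channel intensities after loess and Aquantile. Figures were drawn with matplotlib 3.10.9.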

Results

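Transcript levels were measured in the anterior pituitary of 8 mature gilts (young female pigs) of a Large White by Polish Landrace cross. Of these, 4 were killed on days 12 to 13 of early pregnancy, when the mother's body first responds to the conceptuses, and 4 on days 12 to 13 of the estrous cycle. A corpus luteum is present in both states. Each of 4 two-colour arrays held the RNA of 1 pregnant and 1 cyclic gilt, so a log2 ratio of pregnant over cyclic was obtained 4 times per probe. Pregnant RNA carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4, per the sample labels. Well above background were 47.5% to 67.9% of the spots in Cy3 and 60.7% to 71.8% in Cy5, and no spot was saturated. The number of arrays limits the precision of every value. On array 4 a round area of 5433 spots, 12.4% of the array, was dim. Of its bright spots 84.3% were lost, against 0.2% outside it. The area was drawn as the tiles of 10 by 5 spots that lost at least 25% of their bright spots, so this contrast is partly built in.

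**Figure D1:**
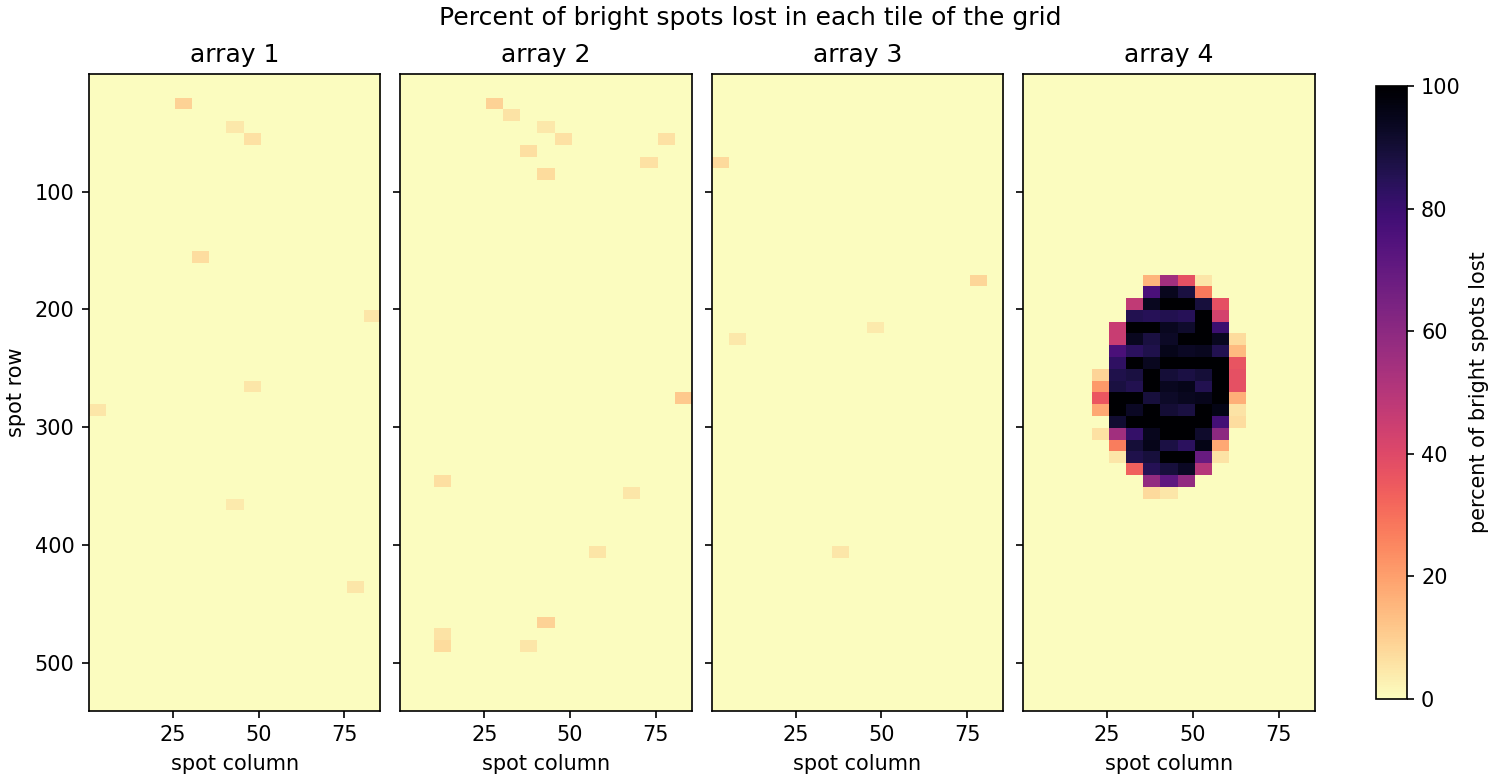
Percent of bright spots lost in each tile of 10 rows by 5 columns of spots, by spot row and spot column, for the 4 arrays. A spot was lost when it lay more than 2 log2 units below the median of the other arrays; on array 4 the lost spots fill a round area, and the whole array lost 10.73% of its bright spots, against 0.03% to 0.12% on the others.

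The comparison asked how the anterior pituitary transcriptome differs between early pregnancy and the same days of the cycle. Among named genes, the log2 ratios with the smallest p in the negative direction belonged to TMOD3, which encodes a cap of actin filaments, and to FOS, an immediate early transcription factor. TMOD3 (NM_214294) had a log2 ratio of -1.61 ± 0.18 (SD, n = 4), 3.06-fold lower in pregnant gilts, and its 4 arrays lay between -1.76 and -1.36. FOS (NM_001123113) had -1.22 ± 0.79 (SD, n = 4), 2.32-fold lower, with -2.02 on array 3 and -0.48 on array 4. Of named genes positive on the 4 arrays, the 8 with the smallest p were taken. The largest ratio among them was that of NR4A3, an orphan nuclear receptor induced early by hormonal stimuli, at 1.94 ± 1.41 (SD, n = 4). OAZ3, an antizyme of polyamine metabolism, followed at 1.59 ± 0.98, and SSTR5, a somatostatin receptor of hormone-secreting cells, at 1.23 ± 0.57. The 3 probes of NR4A3 ran from 0.17 to 1.93, and over the alternatives with the dyes as labelled its ratio ran from 1.16 to 2.21. No probe passed the threshold: of 21627 tested probes, 0 had an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment. The smallest limma adjusted p was 0.0761, for the unnamed transcript DT331878 at a log2 ratio of 2.01 ± 0.19 (SD, n = 4). At an unadjusted p under 0.05 limma listed 3904 probes, 18.1% of those tested, where evenly spread p would give 1081. Probes are not independent, so 1081 does not show what chance can give. Other groupings of the gilts within arrays gave 233, 277, 291, 509, 560 and 4172 probes. Leaving out 1 array gave from 894 of 20256 probes, without array 2, to 6858 of 20323, without array 1. Of the 3904 probes, 2257 were higher and 1647 lower in pregnant gilts, while of the 241 named genes listed 94 were higher and 147 lower.

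The 8 named genes with the smallest p in each direction, taken only from genes of the same sign on the 4 arrays, are therefore values that did not pass. The positive ones also held PTGES, the terminal synthase of prostaglandin E, at a log2 ratio of 0.64 ± 0.28 (SD, n = 4), and RPRD1B at 0.56 ± 0.32. Next came ADAM17, a protease that sheds membrane-bound ligands, at 0.60 ± 0.22, NAXE, a nicotinamide dinucleotide repair enzyme, at 0.44 ± 0.04, and NTF3, a neurotrophin, at 0.60 ± 0.34. The 3 tested probes of ADAM17 disagreed and ran from -0.09 to 0.60. The negative ones held ARF1, a small GTPase of vesicle traffic, at -0.61 ± 0.49, and LDHA, which makes lactate, at -0.45 ± 0.18. They also held the RNA-binding regulator NANOS1 at -0.50 ± 0.33, GGTA1P at -0.48 ± 0.16, the ribosomal protein gene RPL6 at -0.45 ± 0.15 and the imprinted gene PEG10 at -0.64 ± 0.26. Of the 13 tested probes of RPL6, 12 had a negative ratio. The adjusted p of the 16 genes lay between 0.22 and 0.235 in limma. PRL, at a limma p of 0.000655 against 0.000716 for ARF1, was left out of the 8 negative genes by its ratio of 0.01 on array 2. For FOS, ARF1 and NR4A3 the ratios were farther from 0 on arrays 1 and 3 than on arrays 2 and 4, which the fit takes as dye effects of 0.67, 0.42 and -1.09. RPRD1B, NANOS1, RPL6, ADAM17 and OAZ3 split the same way, and PTGES, LDHA, NTF3, GGTA1P and NAXE the reverse way. Only SSTR5, TMOD3 and PEG10 of the 16 genes did not divide by dye orientation. The p used to choose the 16 genes rests on the spread between arrays of the same orientation, so such a division is partly built in. Arrays 1 and 3 hold other gilts than arrays 2 and 4. The dye effect of a gene therefore cannot be told apart from a difference between gilts. The fit takes either out of the residual spread, and FOS had an SE of 0.088 beside its SD of 0.79.

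**Figure D2:**
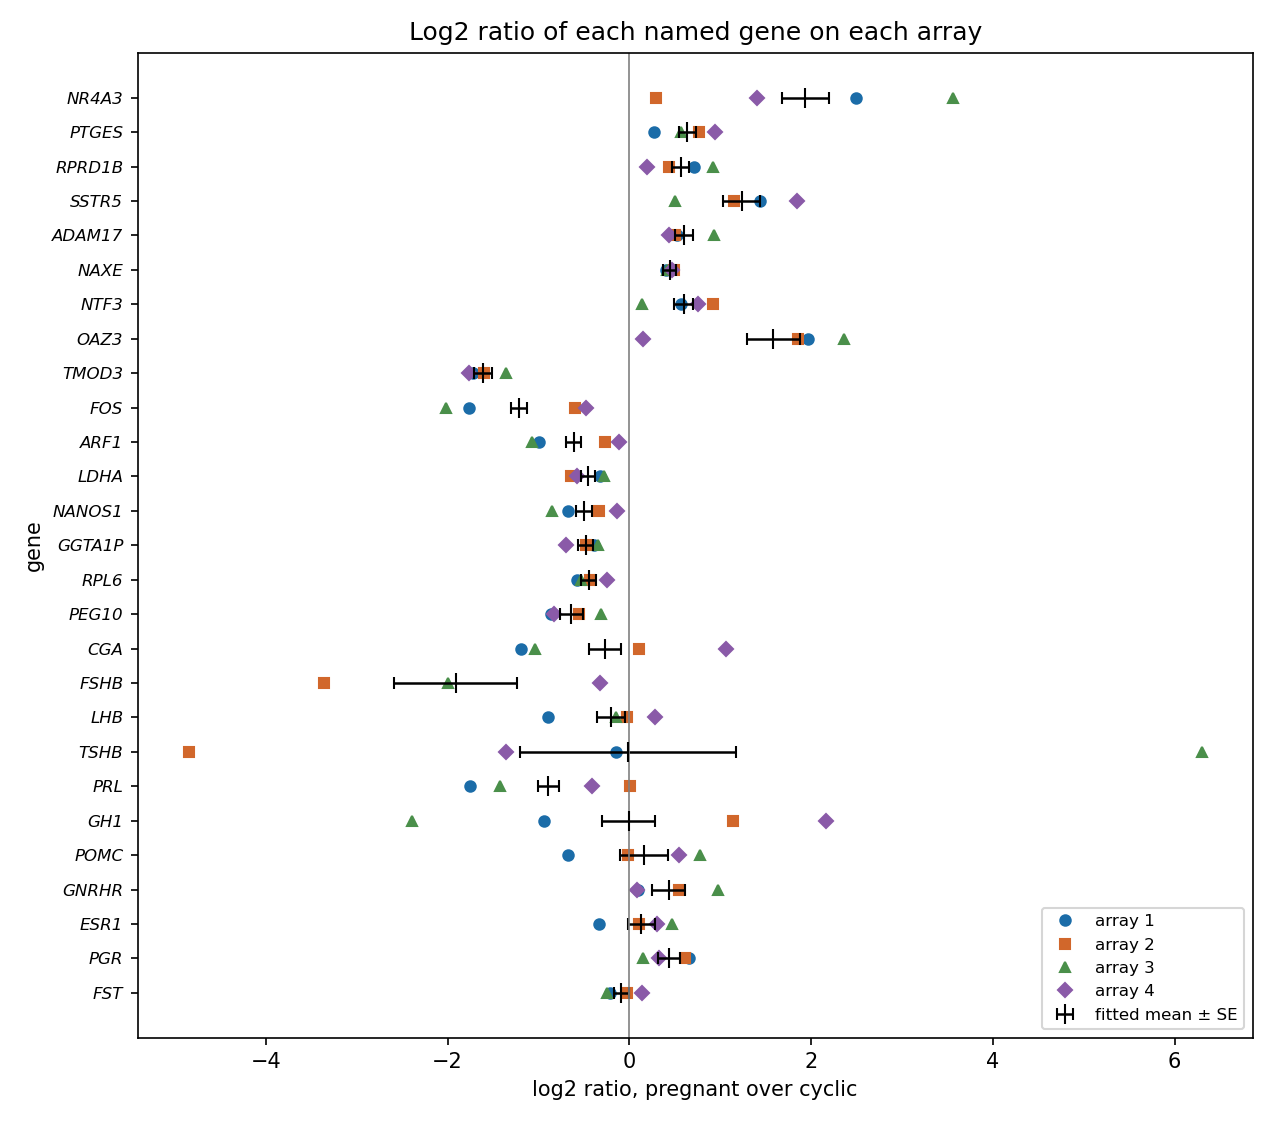
Log2 ratio of pregnant over cyclic gilts (horizontal axis) for the named genes (vertical axis), with 1 marker per array and the fitted mean ± SE in black. The 4 markers of TMOD3 lie between -1.76 and -1.36, while those of TSHB run from -4.85 to 6.30.

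Among the hormone genes of the gland PRL (NM_213926), which encodes prolactin, had a log2 ratio of -0.89 ± 0.83 (SD, n = 4), 1.86-fold lower in pregnant gilts, and its 4 probes gave -1.06 to -0.66. The ratio was -1.75 on array 1, -1.42 on array 3, -0.41 on array 4 and 0.01 on array 2, which the fit takes as a dye effect of 0.69 beside the ratio. A difference between gilts could give this split too, and the fitted SE of 0.114 leaves the split out. FSHB, the beta subunit of follicle-stimulating hormone, had the most negative ratio of the group, -1.91 ± 1.52 (SD, n = 3), 3.76-fold lower. It had -3.36, -1.99 and -0.32 on arrays 2 to 4, and its spot on array 1 was left out as an outlier of the scan software. The other members gave -0.27 ± 1.06 for CGA, the common alpha subunit, -0.20 ± 0.50 for LHB, 0.16 ± 0.64 for POMC and -0.01 ± 2.05 for GH1. TSHB, measured by 1 probe, averaged -0.02 ± 4.66 and was -4.85 on array 2 and 6.30 on array 3. Of the 7 measured hormone genes, 6 had a negative and 1 a positive ratio. Over all probes 0 passed, and 1, PRL, passed when adjusted over the list alone (limma, adjusted p = 0.00459). The list as a whole did not pass camera (adjusted p = 0.351). With the dyes as labelled the sign of GH1 changed in 5 alternatives, that of POMC in 2 and that of TSHB in 3.

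**Figure D3:**
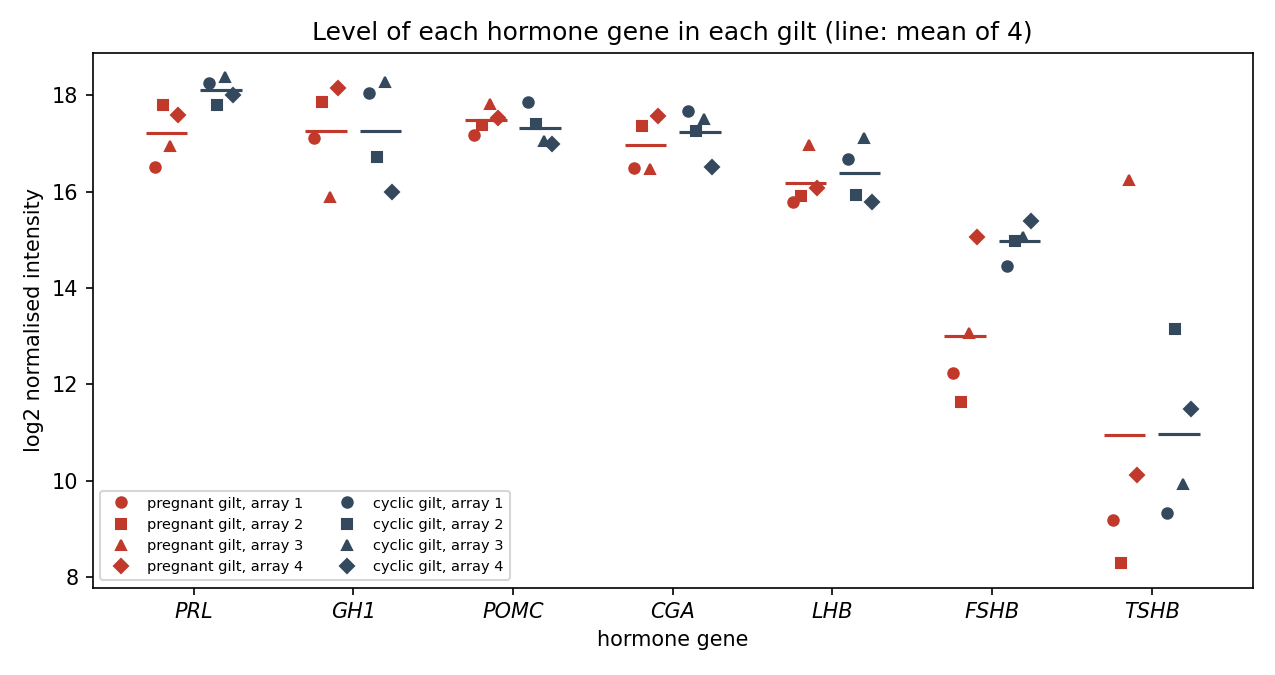
Log2 normalised intensity of the 7 hormone genes in each gilt, pregnant in red and cyclic in dark blue, with the marker shape giving the array and the line the mean of 4 gilts. FSHB lay between 11.63 and 15.06 in pregnant and between 14.46 and 15.38 in cyclic gilts, with its spot of array 1, left out of the test, drawn too; TSHB reached 16.23 in the pregnant gilt of array 3.

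Receptors for hypothalamic factors had mostly positive ratios, 9 of 12 measured genes, but the list median was 0.04. The mean of 0.17 rested on SSTR5, and was 0.07 without it. Beside SSTR5, the receptor of gonadotropin-releasing hormone, GNRHR (NM_214273), had 0.43 ± 0.43 (SD, n = 4) and the thyrotropin-releasing hormone receptor TRHR 0.30 ± 0.28. SSTR5 alone passed when adjusted over the list alone (limma, adjusted p = 0.0242), and the list did not pass camera (adjusted p = 0.172; 0.692 as the adjusted p with an estimated correlation). Of 6 measured genes of GnRH receptor signalling 4 had positive and 2 negative ratios. Among them the MAP kinase kinase gene MAP2K1 had -0.53 ± 0.54 and passed when adjusted over the list alone (limma, adjusted p = 0.0433). The list gave a camera adjusted p of 0.795. Of 4 measured lineage transcription factors all had positive ratios, NR5A1 only 0.03 ± 0.16. POU1F1, which drives the somatotroph, lactotroph and thyrotroph lineages, had 0.46 ± 0.23 and passed when adjusted over the list alone (limma, adjusted p = 0.0346). Immediate early genes went both ways, 6 positive and 5 negative of 11. When adjusted over the list alone 4 passed, NR4A3 and KLF2 (0.47 ± 0.29) upwards and FOS and BTG2 (-0.33 ± 0.24) downwards. The list gave a camera adjusted p of 0.79. None of these genes passed over all probes, and the spots of TRHR and BTG2 on array 4 lie in the dim area.

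Of 8 measured genes of hormone processing and the secretory granule, 7 had negative ratios. Among them were RAB3A, a GTPase of granule release, at -0.32 ± 0.50, and CPE, a prohormone-processing enzyme, at -0.33 ± 0.23 (SD, n = 3). Of the 8 genes 0 passed over all probes or when adjusted over the list alone, and camera gave an adjusted p of 0.175.

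The nuclear progesterone receptor PGR (NM_001166488) had a log2 ratio of 0.44 ± 0.24 (SD, n = 4), positive on the 4 arrays, and the membrane-associated PGRMC1 -0.40 ± 0.28 (SD, n = 3). The estrogen receptor ESR1 had 0.13 ± 0.34. Of 11 measured steroid receptors and coregulators 5 had positive and 6 negative ratios, and of 10 measured genes of steroid synthesis 7 were positive, with AKR1CL1 at 0.33 ± 0.28 and HSD17B4 at -0.24 ± 0.36. In the activin, inhibin and TGF-beta group, 9 of 17 were positive. The signal transducer SMAD3 had 0.37 ± 0.12, the receptor BMPR1B 0.74 ± 0.85 and the activin antagonist FST -0.09 ± 0.18. PTGES passed when adjusted over its prostaglandin list alone (limma, adjusted p = 0.0138), in which 6 of 12 measured genes were positive. No gene of the 3 other lists passed when adjusted over its list alone, and 0 genes of the 4 lists passed over all probes. The camera adjusted p was 0.997 for steroid receptors and 0.79 for each of the other 3 lists.

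Interferon response genes, of interest because conceptuses secrete interferons in this period, had 10 positive and 9 negative ratios among 19 measured. Among them GBP2, an interferon-induced GTPase, had 0.30 ± 0.38 (SD, n = 4). Genes of antigen presentation split 8 to 8, with PSMB10, an immunoproteasome subunit, at 0.40 ± 0.18, SLA-DQA1 at 0.39 ± 0.10 (SD, n = 3) and CD74, the invariant chain, at -0.28 ± 0.59. Among 20 cytokine genes 13 were positive. The chemokine receptor CXCR4 had -0.51 ± 0.33, RELA -0.28 ± 0.05, the cytokine receptor subunit IL6ST 0.27 ± 0.12 and NFKBIA 0.47 ± 0.51, the last with its array 4 spot inside the dim area. No gene of these 3 lists passed over all probes or when adjusted over its list alone, and camera gave adjusted p of 0.428, 0.79 and 0.79.

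Adipokine and orexin genes split 6 to 6 of 12, with LEPROT, which controls leptin receptor at the cell surface, at -0.53 ± 0.45 and ADIPOR1, an adiponectin receptor, at -0.24 ± 0.19 (camera adjusted p = 0.997). Angiogenic factors had 5 positive and 4 negative ratios of 9, led by the hypoxia-inducible EPAS1 at -0.43 ± 0.20 and the receptor MET at -0.24 ± 0.12 (camera adjusted p = 0.834). Of 9 measured cholesterol genes 5 were negative, with MSMO1 at -0.36 ± 0.27 and STARD4 at 0.21 ± 0.21 (camera adjusted p = 0.79). The growth hormone and IGF list had 6 positive and 9 negative ratios of 15, with the receptor IGF1R at -0.17 ± 0.07 and STAT5A at -0.17 ± 0.19 (camera adjusted p = 0.901). The unfolded protein response had 1 and 5 of 6, the chaperone HSP90B1 at 0.14 ± 0.38 and ATF4 at -0.12 ± 0.17 (camera adjusted p = 0.834). Cytosolic ribosomal protein genes were positive for 19 of 27, among them RPS21 at 0.24 ± 0.38 and RPLP0 at 0.24 ± 0.18, with RPL6 against them. The 13 probes of RPLP0 disagreed, 6 being positive. For the list camera gave an adjusted p of 0.165, and 0.0573 as the adjusted p with an estimated correlation. The mean of that list was -0.14 and -0.12 on arrays 1 and 3 and 0.28 and 0.21 on arrays 2 and 4, so its sign followed the dye orientation. Oxidative phosphorylation genes were positive for 8 of 12, with ATP5O at 0.18 ± 0.22 and SDHD, a subunit of succinate dehydrogenase, at -0.40 ± 0.33 (camera adjusted p = 0.225). No gene of these 7 lists passed over all probes or when adjusted over its list alone.

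Markers of the other cells of the gland and of tissue handling were compared the same way. Proliferation genes were negative for 7 of 8, CDK1 at -0.77 ± 0.86, CCNB1 at -0.72 ± 0.81 and TOP2A at -0.77 ± 1.03 (SD, n = 4). The cyclic gilt of array 3 stood apart, with log2 intensities of 8.75 for TOP2A and 9.26 for CDK1, against 6.54 to 7.44 and 7.25 to 8.10 in the other 7. The list mean was -1.09 on array 3 and 0.01 on array 4, and the list gave a camera adjusted p of 0.172, and an adjusted p above 0.8 with an estimated correlation. Stromal and pericyte markers were negative for 6 of 8, with SPARC at -0.62 ± 0.28 (SD, n = 3), ACTA2 at -0.36 ± 0.19, its array 4 spot in the dim area, and FBN1 at -0.30 ± 0.21 (camera adjusted p = 0.172; 0.438 as the adjusted p with an estimated correlation). Endothelial markers were negative for 5 of 8, with ENG at -0.35 ± 0.35 and PECAM1 at 0.20 ± 0.31 (camera adjusted p = 0.79). The 3 tested probes of PECAM1 ran from -0.26 to 0.20, and only 1 was positive. Myeloid markers were positive for 3 of 9, with CD163 at -0.20 ± 0.23 (SD, n = 3) and AIF1 at 0.19 ± 0.21, its array 4 spot in the dim area (camera adjusted p = 0.997), and lymphocyte markers for 3 of 6, with CCL5 at 0.32 ± 0.28 and CD79A at -0.26 ± 0.21 (camera adjusted p = 0.795). Folliculostellate and stem cell markers were negative for 5 of 7, with ANXA1 at -0.48 ± 0.54 (SD, n = 3) and CDH1 at -0.12 ± 0.20 (camera adjusted p = 0.79). Neural and intermediate lobe markers were positive for 3 of 5, with AQP4, likewise in the dim area on array 4, at 0.27 ± 0.52 and MBP at -0.20 ± 0.56 (SD, n = 3; camera adjusted p = 0.79), and the erythrocyte list had 0 measured genes. Of 11 heat shock and hypoxia genes 5 had positive and 6 negative ratios, with HSP90AA1 at -0.22 ± 0.05 (SD, n = 3). LDHA passed when adjusted over the list alone (limma, adjusted p = 0.0235), with a camera adjusted p of 0.79 for the list, and no other gene of these 8 lists passed over its list or over all probes.

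**Figure D4:**
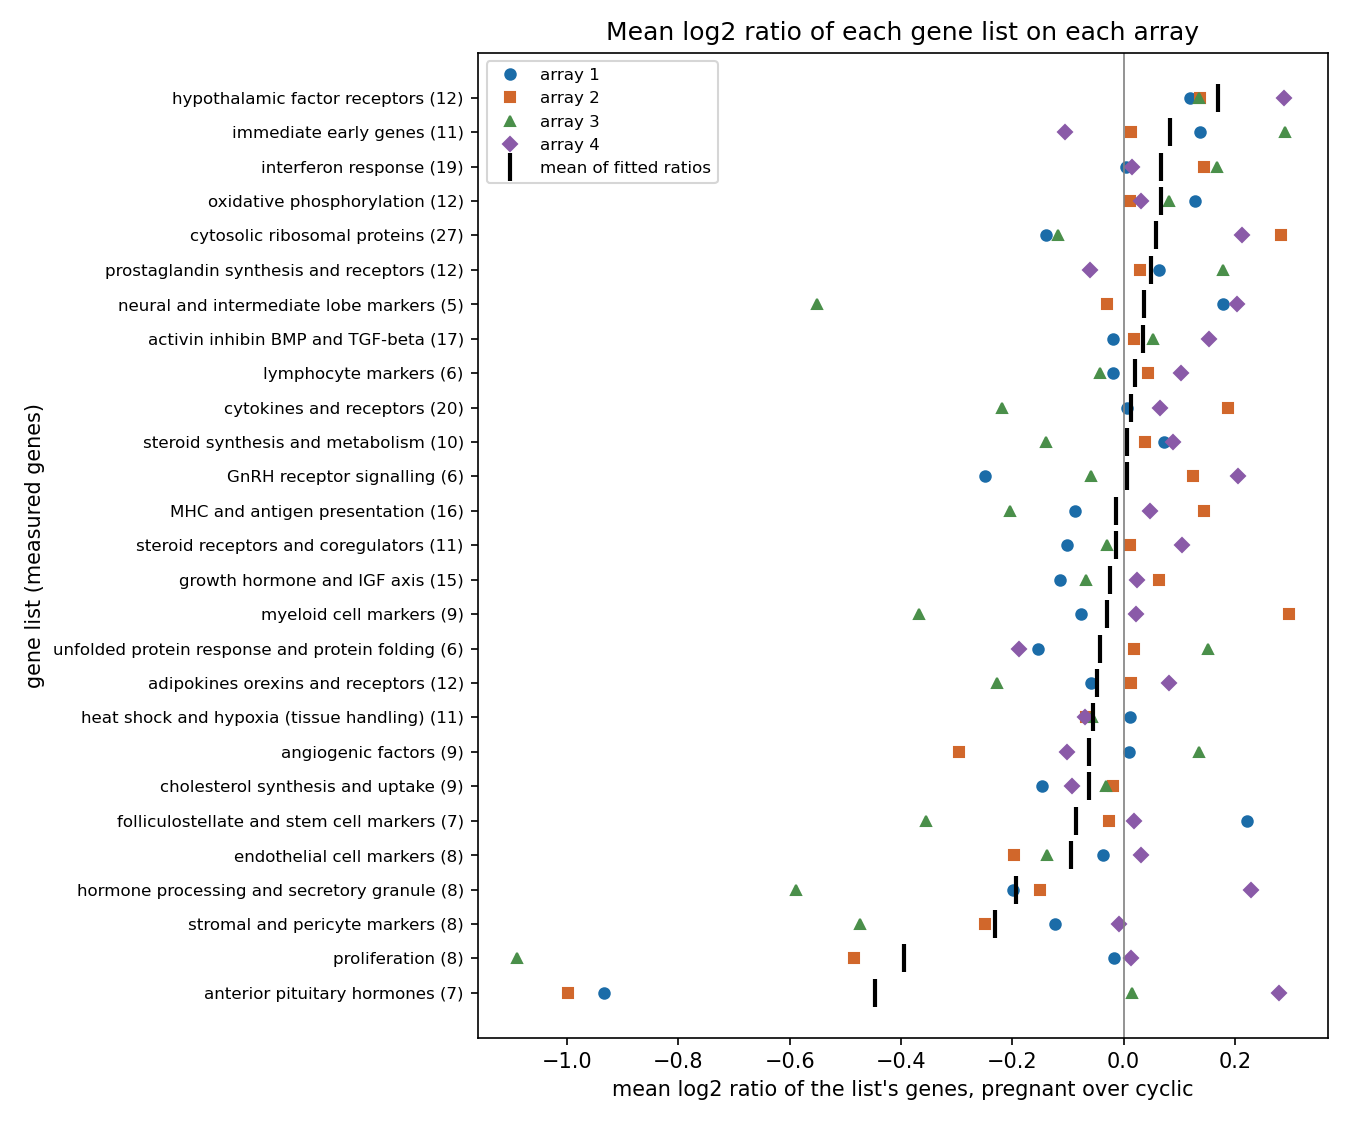
Mean log2 ratio of pregnant over cyclic gilts (horizontal axis) of the measured genes of each list (vertical axis, number of genes in brackets), with 1 marker per array and a black bar for the mean of the fitted ratios. The proliferation list ran from -1.09 on array 3 to 0.01 on array 4, and the hypothalamic factor receptors lay above 0 on the 4 arrays.

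None of the 27 lists tested passed camera, with a preset or an estimated correlation, and none passed fry, which asks whether the genes of a list move on balance one way. For change in either direction the p of fry ran from 7.42e-05, for heat shock and hypoxia (7 of 11 genes in fry), to 0.885, for neural markers (3 of 5 genes). It was 0.000265 for angiogenic factors and 0.00125 for stromal markers. These p of fry were not adjusted over the lists. That none passed fry covers only its test of a move in a single direction. The count of 0 probes depended on the model: a separate-channel fit of the 8 gilts called 1046 probes, 654 of them higher, and without the array of replicate 1 the ratio fit called 3401, against 0 to 4 on leaving out any other array. Median centring in place of loess left the count at 0 but moved the share of higher among probes at an unadjusted p under 0.05 from 57.8% to 82.2%, and it called 2 lists, proliferation downwards (adjusted p = 0.00603) and cytosolic ribosomal proteins upwards (adjusted p = 0.000234), both in limma's camera test.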

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

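The tests of explanations in this part were chosen after the results were seen. Among 117 sets of 4 values, 5 held a value far from the other 3 by Dixon's ratio, where chance gives about 1 in 20, or 5.8.

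Array 4 lost 10.73% of its bright spots, against 0.03% to 0.12% on the other arrays, nearly all of them in the round area. If the 2 gilts of array 4 lacked these transcripts, spots outside the area for the same accessions would be dim too; over 597 accessions with bright spots on both sides, the median difference from the other arrays was 0.75 log2 units outside and -5.24 inside, which argues against this. Inside the area 86.4% of these spots were lost and outside 0.05%. The area was drawn as the tiles that lost at least 25% of their bright spots, so the loss inside is partly built in. The tiles met to form 1 round area, which the rule did not require, and this goes with a local failure of hybridisation or washing. Which step failed stays open. With the area masked, 23771 probes were tested, 0 were called and 3984 had an unadjusted p under 0.05.

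NFKBIA had a log2 ratio of -0.29 on array 4, in the dim area, against 0.69 to 0.80 on the others, and 0.72 with the area masked. ADAM17 had 0.93 on array 3, against 0.44 to 0.52. The mean of the hypothalamic factor receptor list was 0.288 on array 4, against 0.119 to 0.138. The mean of the heat shock and hypoxia list was 0.012 on array 1, against -0.07 to -0.056.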

How the results depend on the processing

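The log2 ratio of each of 79 named genes was recomputed under up to 20 settings. With the dyes as labelled, at most 6 signs changed under any 1 setting. Under 6 settings, such as Aquantile and the trend and robust prior, no ratio of a named gene changed at all, so these do not test the signs. The count of probes called, 0 in the main setting, was 1 with no background subtraction, with an offset of 16, with a trend and robust prior and with array quality weights, 2 without the dye coefficient (1 of them TMOD3, adjusted p = 0.0429), 2 genes with the mean over the probes of a gene (TMOD3 and FOS, adjusted p = 0.0287 and 0.031), and 1046 in the separate-channel fit. TMOD3 and FOS have 1 tested probe each, so the mean over probes left their ratios as they were. In that setting p was adjusted over 1744 genes, not over 21627 probes. Over the settings the adjusted p of TMOD3 ran from 0.00108 to 0.981 and that of FOS from 0.00142 to 0.853. The 0.981 came with pregnant RNA in Cy3 on all arrays. With the dyes as labelled the ratio of TMOD3 ran from -1.89 to -1.50. TMOD3 also passed without array 3 (limma, adjusted p = 0.032). Of the named genes, 22 of 70 passed in the separate-channel fit and 31 of 75 without array 1. The count was 3390 at an unadjusted p under 0.05 with at least 1.2-fold. Leaving out each array gave 0 to 3401 called probes and 894 to 6858 at an unadjusted p under 0.05. The highest of both came without array 1, when array 3 is alone in its dye orientation and the residual comes from arrays 2 and 4. Without array 3 the residual likewise comes from arrays 2 and 4, and the counts were 4 and 3550, so the residual alone does not account for it. The ratios of array 3 had the largest SD over tested probes, 0.581, against 0.276 to 0.333 on the others. Whether this accounts for the high counts was not tested. The count at an unadjusted p under 0.05 was 2555 with median centring and 1012 with pregnant RNA in Cy3 on all arrays, and between 3097 and 5844 otherwise. Gene lists called, 0 in the main setting, were 2 with median centring, 1 with pregnant in Cy3 on all arrays and 0 to 3 on leaving out each array: without array 1 proliferation at an adjusted p of 0.00827, and without array 4 secretory granule, proliferation and ribosomal proteins, each at an adjusted p of 0.0441; with the preset correlation the adjusted p of the proliferation list ran from 0.00603 to 0.808 over the settings and that of the ribosomal list from 5.91e-05 to 0.703, the 5.91e-05 being downwards, with pregnant in Cy3 on all arrays, and the list upwards in all others. With pregnant in Cy3 on all arrays the share of higher probes was 40.1% and 25 genes changed sign by more than their SD: PTGES -0.22, SSTR5 -0.26, NAXE -0.034, NTF3 -0.24, TMOD3 0.07, LDHA 0.15, GGTA1P 0.11, PEG10 0.05, FSHB 0.56, PGR -0.032, SMAD3 -0.077, BMPR1B -0.46, SLA-DQA1 -0.15, EPAS1 0.068, SPARC 0.15, RPS21 -0.33, RPLP0 -0.14, MSMO1 0.005, PGRMC1 0.10, CCL5 -0.14, CD163 0.27, AIF1 -0.082, CDH1 0.087, MBP 0.50 and HSP90AA1 0.073; by construction this setting takes a dye effect for a group difference. Otherwise only HSP90AA1 did, at 0.12 with median centring. The causes of the other shifts were not tested. The ratio fit is paired by array, since each ratio sets 1 pregnant against 1 cyclic gilt, and the separate-channel fit takes the array into account by its intraspot correlation.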

Other observations

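The tests of explanations and the split counts in this part were chosen after the results were seen.

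AMY2, which encodes an alpha-amylase and was singled out after its values were seen, was far higher in 1 cyclic gilt than in the other 7. The median log2 intensity of its probes was 15.61 in the cyclic gilt of array 3, and the medians of the other gilts lay between 9.20 and 11.67. The rise was 4.69 log2 units, 25.9-fold, over the median of the other gilts. A defect of single spots would raise few probes, while 100% of the 23 AMY2 probes were raised by at least 2 log2 units. RNA from exocrine pancreas would bring its other abundant transcripts: the 25 probes of 8 such genes rose by -0.03 in the median and by at most 0.30, and the 7 PNLIP probes stood at 6.20 in that gilt against 6.21 in the others. RNA from salivary gland would raise BPIFA2, which stood at 6.17 against 6.19, and the 24 probes of 8 salivary marker genes rose by 0.01 in the median. The highest rise among them was 1.13, for LYZ, which is also a myeloid marker, and the highest of another gene 0.41. The tables thus argue against these 3 sources; other sources of AMY2 RNA and a difference between animals stay open, and no biological explanation was tested. The same gilt had the highest levels of TOP2A (8.75) and CDK1 (9.26), and whether this is linked to AMY2 was not tested.

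The dyes of the sample labels and of the labelling protocol disagree. If pregnant RNA had been in Cy3 on all 4 arrays, dye bias and a shared group difference alike would make the Cy5 over Cy3 ratios of any pair of arrays correlate above 0 across probes. In the 4 pairs of arrays with opposite labelled dyes they correlated between -0.393 and -0.019 across tested probes, which are not independent replicates, while the other pairs averaged 0.396. This argues against pregnant RNA in Cy3 on all 4 arrays. Turned by the sample labels, array 4 correlated with arrays 1 and 3 by only 0.075 and 0.019 and with array 2 by 0.347, and masking its dim area gave 0.076, 0.020 and 0.355.

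Of 19880 probes measured on 4 arrays, 25.9% had the same sign on all of them, where independent signs give 12.5%. With a dye effect in the model the gilts can be regrouped within arrays in 7 ways, the real one included, which is too few for a share under 0.05. The real grouping gave 3904 probes at an unadjusted p under 0.05 and the highest other 4172, so 2 of the 7 gave as many. That other grouping exchanges the gilts of array 1 and leaves array 3 alone in its dye orientation. The remaining groupings gave 233 to 560 probes. For probes called, all 7 gave 0 in limma, and the highest other was 0. For gene lists called the real value was 0 and the highest other 4, so all 7 gave as many. With a real value of 0 these 2 comparisons could come out no other way, so they decide nothing.

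TSHB spanned 7.94 log2 units between gilts, from 8.29 to 16.23, more than any other hormone gene, and rests on 1 probe. GH1 was lower in the pregnant gilt on arrays 1 and 3 (-0.94 and -2.39) and higher on arrays 2 and 4 (1.14 and 2.16), a split that follows the dyes, with a fitted dye effect of 1.66. Arrays 1 and 3 hold other gilts than arrays 2 and 4, so a difference between gilts could give this split too.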
